A study of Homo sapiens with 15 samples.

How the data were processed

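RNA was measured in 9 samples of HUVEC and 6 of exosomes, 15 arrays in all. Per the labels' protocols, Jurkat and JinB8 exosomes were precipitated with an ExoQuick kit from conditioned medium, HUVEC were kept with them for 6 h in EGM2 medium, and total RNA including small RNAs was extracted with a miRNeasy kit. By the same protocols 300 ng of total RNA per sample were labelled with whole-transcript expression and terminal labelling kits, with biotin as the label. Per the submitters' processing notes the arrays were processed with Affymetrix Expression Console; its version, the background correction, the normalization and the set of arrays normalized together are not given in the sources used here. The deposited values are on the log2 scale by their range and distribution, with no missing values, and come without detection calls, so signal could not be set against background. Whether the deposited values of all groups were normalized together is unknown: the medians of the array sets averaged 6.97 in untreated HUVEC, 5.14 and 5.11 in HUVEC with JK and JINB8 exosomes, and 5.11 and 5.12 in JK and JINB8 exosome RNA, which quantile normalization over all 15 would not leave.

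The table held 33297 probesets. In the platform annotation 19460 had 1 gene symbol, 1754 had several and 12083 were not listed and stayed unnamed. By Entrez identifier 19429 of the named probesets matched the gene reference, which changed 0 symbols. Each gene took its probeset with the highest mean over the 15 arrays, which left 18417 genes, 769 of them with more than 1 probeset. Among called genes with several probesets another probeset was called in the opposite direction for 33 of 378 genes with JK exosomes against untreated HUVEC, 36 of 395 with JINB8 exosomes, and 0 of 18 in exosome RNA. No genome coordinates were used. Transcripts that share sequence, such as histone, ribosomal protein and mitochondrial copies, are uncertain as single genes.

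Groups came from the sample labels. HUVEC contrasts were fitted in 1 limma model over the 9 HUVEC arrays (lmFit and eBayes, no trend, not robust, 6 residual degrees of freedom), and exosome RNA in a model of its own over 6 arrays (4 residual degrees of freedom), with Benjamini-Hochberg adjustment over 18417 genes and a threshold of 0.05. Standard errors are limma's moderated ones. Of 35 gene lists, written with the tests and the naming rule before the data were examined, 33 had at least 5 measured genes and were tested with camera (correlation 0.01), camera with an estimated correlation, and fry, adjusted over the lists of a comparison. The other 2 had too few measured genes. R 4.3.3 and limma 3.58.1 were used.

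The text names, per comparison, genes from the 10 highest and 10 lowest log2 fold changes among genes with adjusted p under 0.05 whose groups do not overlap. With fewer than 10 such genes it takes all of them and the 5 highest and 5 lowest with an unadjusted p under 0.01, given as not passing. It adds CD47, SIRPA, THBS1, KDR, FLT1 and VEGFA, and up to 4 members with the smallest p of each list that passes or has a passing member. LOC, ORF and blank symbols are passed over. For the comparisons with untreated HUVEC the rule was applied to values quantile-normalized over the 9 HUVEC arrays, a choice made after the array levels were seen. With 3 against 3 arrays chance separates the values of 10% of genes, and an exact two-sided permutation test cannot give a p below 0.1.

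On simulated arrays built from the real means and spreads with 200 changed genes among 18417, 65.7%, 97% and 100% of genes changed 1.5-fold, 2-fold and 3-fold were recovered for JK-treated against untreated HUVEC, with 12 false calls. For JINB8-treated against JK-treated HUVEC the shares were 74.6%, 95.5% and 100% with 11 false calls, and for exosome RNA 77.6%, 100% and 98.5% with 11 false calls. For JINB8-treated against untreated HUVEC they were 73.1%, 95.5% and 98.5% with 8 false calls. In each simulation the 1 shifted list was called and 0 of 32 unshifted lists were. The noise was drawn independently for each gene and array, which leaves out genes that vary together and any structure shared by arrays. So the simulations do not show how the list test, or the shares recovered, would hold on the real arrays.

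Alternatives set before the data were examined were quantile normalization, median centring, leaving out the 40% dimmest genes, all rows of the table, the mean of a gene's probesets, a variance trend with robust fitting, array weights, the replicate number as a block, all 15 arrays in 1 fit, the 6 compared arrays alone, an unadjusted p under 0.05 with a fold change of 1.5, and leaving out each array. Cyclic loess and the quantile basis for the comparisons with untreated HUVEC were added after the data were seen.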

Results

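Gene expression was measured on Affymetrix whole-transcript gene arrays in human umbilical vein endothelial cells (HUVEC) and in RNA taken from exosomes, the small vesicles that cells release into their medium. The exosomes came from Jurkat, a human T cell leukaemia line written JK in the sample names, or from JinB8 (JINB8), a CD47-deficient Jurkat mutant. CD47 is a cell surface receptor for thrombospondin-1 and a ligand of SIRPA. The 15 arrays fell into 5 groups of 3: untreated HUVEC, HUVEC kept for 6 h with JK exosomes, HUVEC kept for 6 h with JINB8 exosomes, RNA of JK exosomes, and RNA of JINB8 exosomes. The number of arrays limits the precision. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

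The deposited levels of the arrays were not alike. The array medians of untreated HUVEC averaged 6.97 ± 0.06 (SD, n = 3) on the log2 scale, against 5.14 ± 0.03 with JK exosomes and 5.11 ± 0.02 with JINB8 exosomes. The exosome RNA arrays averaged 5.11 ± 0.03 for JK and 5.12 ± 0.01 for JINB8. Values within a group correlated across probesets at 0.986 to 0.995, JK-treated with JINB8-treated HUVEC at 0.990 to 0.993 (probesets are not independent replicates), and treated with untreated HUVEC at 0.953 to 0.965.

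**Figure D1:**
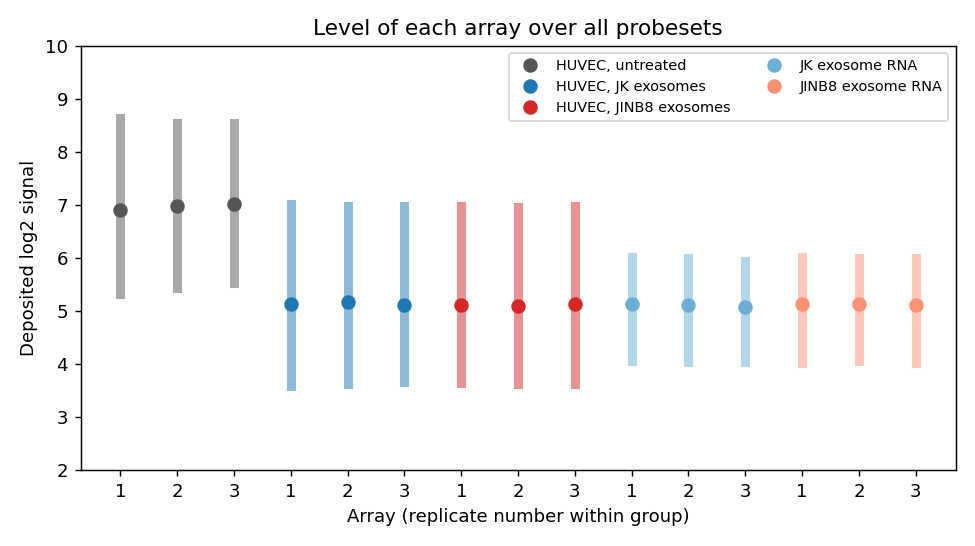
Deposited log2 signal of each of the 15 arrays over all probesets, with the median as a point and the range from the first to the third quartile as a bar, coloured by group. The 3 untreated HUVEC arrays have medians of 6.91 to 7.03, above those of all other arrays, which lie between 5.08 and 5.18.

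The first comparison asked how endothelial cells differed after exposure to exosomes of CD47-bearing T cells. As deposited, 18319 of 18417 genes differed between JK-treated and untreated HUVEC (30 higher and 18289 lower, limma, Benjamini-Hochberg adjusted p under 0.05), and the median gene was lower by a log2 change of -1.68. The values that follow are therefore relative to this array-wide shift, after quantile normalization of the 9 HUVEC arrays, a basis chosen after the levels of the arrays were seen. On it 8950 genes changed, 4829 higher and 4121 lower (6462 and 3587 with median centring), and 1054 of them changed at least 2-fold. Because the untreated arrays stood on a level of their own, batch and treatment cannot be told apart in either comparison with them.

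Relative to the shift, the steepest rises in JK-treated HUVEC by the naming rule included ST8SIA6, a sialyltransferase (log2 fold change 3.70 ± 0.12, SE, n = 3 per group, adjusted p = 3.73e-09), and ADM, which encodes the vasodilator peptide adrenomedullin (3.09 ± 0.27, adjusted p = 5.54e-06). IFIT2, an interferon-induced gene, rose by 2.90 ± 0.30, and the glucose transporter SLC2A1 by 2.73 ± 0.13. TXNIP and ARRDC3, members of the arrestin-domain family, rose by 2.57 ± 0.32 and 2.74 ± 0.12. The growth factor genes BMP4 and GDF3 rose by 2.56 ± 0.09 and 2.67 ± 0.41, and the ceramidase gene ACER2 by 2.66 ± 0.08. The steepest fall was that of TAGLN, an actin-binding protein of contractile cells (-5.06 ± 0.10, adjusted p = 1.38e-10). CD34, a surface sialomucin of endothelial and stem cells, changed by -4.67 ± 0.11. The activin inhibitor FST changed by -4.17 ± 0.13, the keratin KRT7 by -4.01 ± 0.15 and the Notch target HEY2 by -3.94 ± 0.13. PTGS2, the inducible cyclooxygenase, and SELE, the adhesion molecule E-selectin, changed by -3.91 ± 0.08 and -3.85 ± 0.37. CCNA1, IL7R and CHRNA1 changed by -3.90 ± 0.13, -3.88 ± 0.16 and -3.84 ± 0.12. Each of these genes had an adjusted p of 0.000301 or less. Some ranked low in signal on at least 1 HUVEC array: IL7R at 18254, ST8SIA6 at 16358, IFIT2 at 16217 and TAGLN at 15527 of 18417 genes. SLC2A1 and ARRDC3 ranked no lower than 2304 and 3833. Without detection calls low signals cannot be set against background, so the sizes of such changes, here and with JINB8 exosomes, are uncertain.

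Of 33 lists tested with camera at a preset correlation of 0.01, 14 passed after quantile normalization, 4 upward and 10 downward. Counts adjusted over the list alone were the same unless given. Of the 26 glycolysis and hypoxia genes, 23 rose and 3 fell (adjusted p = 5.55e-09, adjusted p = 0.214 with an estimated correlation), though as deposited their median was -0.41. ENO2, SLC2A3 and ALDOC rose by 1.91 ± 0.08, 1.89 ± 0.08 and 1.71 ± 0.09 (ALDOC 0.056 as deposited, not passing). Of the 32 genes of NF-kB and endothelial inflammatory activation, 24 fell and 3 rose (adjusted p = 6.91e-08). The cytokine gene CXCL8 changed by -3.18 ± 0.14, IL1A by -3.06 ± 0.12, the adhesion molecule VCAM1 by -2.88 ± 0.10 and TRAF1 by -2.09 ± 0.10. This list and that of TGF-beta, YAP and matrix response held with an estimated correlation (adjusted p = 0.025 for both), and the other 12 did not. Of the 31 TGF-beta, YAP and matrix genes, 22 fell and 2 rose (adjusted p = 5.06e-06), among them TGFBI (-2.30 ± 0.09), SMAD6 (-1.93 ± 0.10), ID1 (-1.82 ± 0.11) and the receptor TGFBR1 (-1.63 ± 0.07). Median centring ended the call of that list (adjusted p = 0.0931).

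Of the 31 G2/M and mitosis genes, 27 fell and none rose (28 and 0 adjusted over the list alone, adjusted p = 7.44e-10, adjusted p = 0.314 with an estimated correlation). KIF23, MKI67 and AURKB changed by -2.03 ± 0.14, -1.46 ± 0.15 and -1.21 ± 0.07. Of the 35 DNA replication genes 16 fell and 5 rose (17 and 5 adjusted over the list alone), with GINS2 at -1.40 ± 0.13 and RFC3 at -1.19 ± 0.10 (adjusted p = 0.00967, adjusted p = 0.638 with an estimated correlation). Among 21 endothelial tip cell markers 16 fell and 5 rose, with PLAUR, the urokinase receptor, at -2.01 ± 0.12 and UNC5B at -1.13 ± 0.08 (adjusted p = 0.000909, adjusted p = 0.314 with an estimated correlation). Of the 30 immediate early genes 16 fell and 5 rose, with FOSL1 at -1.31 ± 0.09 and NR4A1 at -1.20 ± 0.08 (adjusted p = 0.00138, adjusted p = 0.0827 with an estimated correlation). Of the 26 genes of VEGF, Notch and other endothelial growth factor signalling 13 fell and 6 rose, with HEY1 at -2.48 ± 0.14 and JAG1 at -1.58 ± 0.08 (adjusted p = 0.0471, adjusted p = 0.314 with an estimated correlation). Of the 18 NRF2 and metallothionein genes 11 fell and 3 rose, with MT1X at -1.92 ± 0.15 and the haem oxygenase HMOX1 at -1.49 ± 0.14 (adjusted p = 0.00673, adjusted p = 0.314 with an estimated correlation). Of the 20 cholesterol synthesis genes 7 fell and 2 rose, with HMGCS1 at -1.28 ± 0.10 and SQLE at -0.96 ± 0.11 (adjusted p = 0.0365, adjusted p = 0.621 with an estimated correlation, list median -0.13 but 0.06 with median centring). Among 73 mitochondrial ribosomal protein genes 22 fell and 7 rose, 21 and 7 adjusted over the list alone (adjusted p = 0.022, adjusted p = 0.621 with an estimated correlation, list median -0.10 but 0.03 with median centring). Median centring ended the calls of the last 4 lists (adjusted p of 0.0756 to 0.324).

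Both lists of small nucleolar RNAs, which guide the modification of other RNAs, passed upward relative to the shift, though their medians were -1.14 and -1.46 as deposited. Of 131 members of the C/D box list, which also holds 16 small Cajal body RNAs (SCARNA) of both box types, 63 rose and 9 fell (63 and 11 adjusted over the list alone, adjusted p = 6.19e-05, adjusted p = 0.314 with an estimated correlation). Without the small Cajal body RNAs 55 of 115 rose and 7 fell. Of 61 H/ACA box members 27 rose and 2 fell (adjusted p = 0.00269, adjusted p = 0.214 with an estimated correlation). SNORD94 and SNORA38 had log2 fold changes of 1.44 ± 0.10 and 0.99 ± 0.08. Of 61 cytoplasmic ribosomal protein genes, with a median of -1.08 as deposited, 29 rose and 9 fell (33 and 9 adjusted over the list alone). RPS29 had 1.98 ± 0.11 (0.11 as deposited, not passing) and RPS6 had 1.63 ± 0.07. The list had an adjusted p = 0.00748, and an adjusted p = 0.638 with an estimated correlation. The list of mural cell and fibroblast markers, which holds TAGLN, did not pass (adjusted p = 0.125), with 3 of 18 members higher and 7 lower. The T cell markers did not pass either (adjusted p = 0.684). On the deposited values 10 lists passed against the other genes, NF-kB downward (adjusted p = 0.0123, but adjusted p = 0.508 with an estimated correlation) and 9 upward. The latter included glycolysis and hypoxia (adjusted p = 5.13e-73) and the C/D box list (7.19e-23). They also included interferon-stimulated genes (2.07e-23, adjusted p = 0.323 with an estimated correlation), which did not pass after quantile normalization (adjusted p = 0.237).

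**Figure D2:**
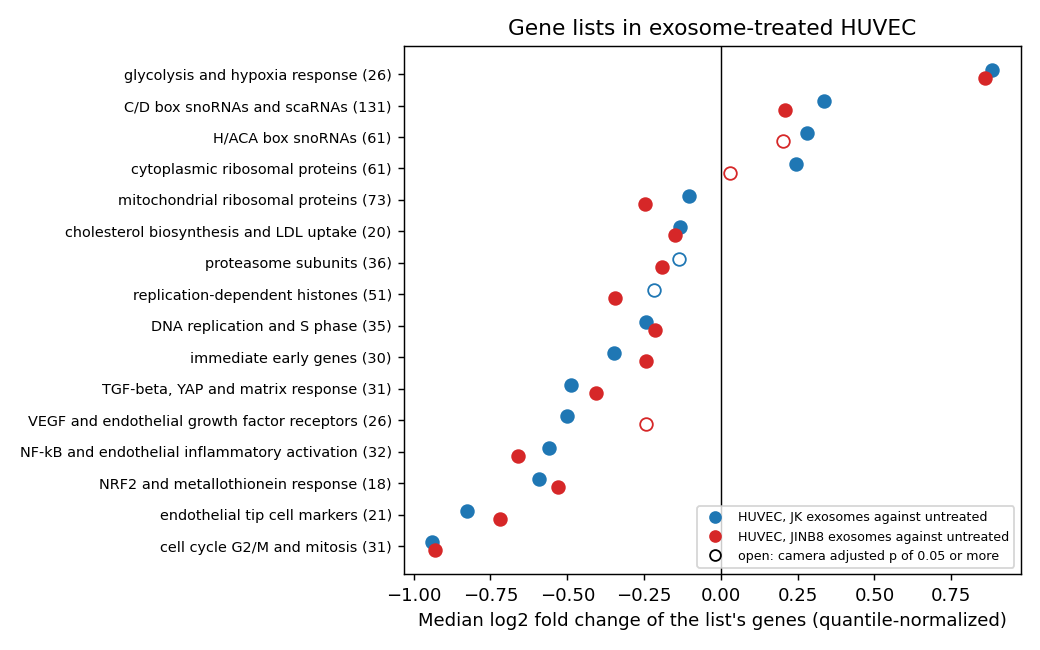
Median log2 fold change after quantile normalization of the genes of each list that passed camera in at least 1 of the comparisons with untreated HUVEC, with list sizes in brackets, JK exosomes in blue and JINB8 exosomes in red (3 arrays per group), and the C/D box list including 16 small Cajal body RNAs (scaRNAs). Glycolysis and hypoxia genes lie highest (0.88 and 0.86) and G2/M genes lowest (-0.94 and -0.93), and in the deposited values, before normalization, the medians of all lists shown were negative.

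The second comparison set HUVEC with exosomes of the CD47-deficient line against the same untreated cells. As deposited, 18286 genes differed (34 higher and 18252 lower, median log2 change -1.71), and 9074 after quantile normalization (4791 higher and 4283 lower, or 7025 and 3450 with median centring, and 1117 at least 2-fold). ST8SIA6 rose by 3.83 ± 0.12 (adjusted p = 4e-09), ADM by 3.18 ± 0.27, GDF3 by 3.09 ± 0.41 and IFIT2 by 3.05 ± 0.30. SESN3, a stress-induced sestrin, rose by 2.96 ± 0.28, ARRDC3 by 2.88 ± 0.12, SLC2A1 by 2.84 ± 0.13 and BMP4 by 2.63 ± 0.09. TAGLN changed by -4.96 ± 0.10 (adjusted p = 2.13e-10), CD34 by -4.38 ± 0.11, KRT7 by -4.33 ± 0.15 and FST by -4.22 ± 0.13. SELE changed by -4.07 ± 0.37, CCNA1 by -3.97 ± 0.13, CYTL1 by -3.85 ± 0.09, HEY2 by -3.80 ± 0.13 and PTGS2 by -3.76 ± 0.08.

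In this comparison 13 lists passed camera after quantile normalization, 2 upward and 11 downward, and 9 on the deposited values, where NF-kB (adjusted p = 0.0155, but adjusted p = 0.605 with an estimated correlation) was again the one lower than the other genes. Of the 26 glycolysis and hypoxia genes 22 rose and 3 fell (23 and 3 adjusted over the list alone, adjusted p = 9.61e-09, adjusted p = 0.271 with an estimated correlation, median -0.31 as deposited), with ENO2 at 1.93 ± 0.08 and SLC2A3 at 1.78 ± 0.08. Of the 131 members of the C/D box list 50 rose and 9 fell (50 and 8 adjusted over the list alone, adjusted p = 0.00161, adjusted p = 0.431 with an estimated correlation, median -1.22 as deposited). Of the 32 NF-kB and inflammatory genes 24 fell and 3 rose (25 and 4 adjusted over the list alone, adjusted p = 1.04e-07), with IL1A at -3.23 ± 0.12, CXCL8 at -3.08 ± 0.14, VCAM1 at -2.98 ± 0.10 and TRAF1 at -2.40 ± 0.10. Of the 31 TGF-beta, YAP and matrix genes 19 fell and 4 rose (20 and 4 adjusted over the list alone, adjusted p = 0.00016), with ID1 at -2.23 ± 0.11 and TGFBI at -2.21 ± 0.09. Both held with an estimated correlation (adjusted p = 0.0461 for each), and median centring ended the call of the second (adjusted p = 0.318). Of the 31 G2/M genes 27 fell and none rose (28 and 0 adjusted over the list alone, adjusted p = 3.22e-09, adjusted p = 0.431 with an estimated correlation), with KIF23 at -1.95 ± 0.14 and AURKB at -1.28 ± 0.07. Of 51 replication-dependent histone genes 23 fell and 6 rose, with H2BC14 at -3.03 ± 0.25 and H2AC21 at -2.02 ± 0.13 (adjusted p = 0.0236, adjusted p = 0.715 with an estimated correlation). Histone genes are near-identical copies, so single members are uncertain. Of the tip cell markers 15 fell and 5 rose (adjusted p = 0.00116, adjusted p = 0.431 with an estimated correlation), with PLAUR at -2.11 ± 0.12 and CXCR4 at -1.53 ± 0.12. Of the immediate early genes 14 fell and 4 rose (adjusted p = 0.00474, adjusted p = 0.133 with an estimated correlation), with KLF6 at -1.42 ± 0.09. Of the DNA replication genes 15 fell and 7 rose (17 and 8 adjusted over the list alone, adjusted p = 0.0139, adjusted p = 0.686 with an estimated correlation), with GINS2 at -1.67 ± 0.13. Of the NRF2 and metallothionein genes 11 fell and 3 rose (adjusted p = 0.0139), and of the mitochondrial ribosomal protein genes 34 fell and 2 rose (adjusted p = 0.000208), with adjusted p = 0.431 with an estimated correlation for both. Of 36 proteasome genes 15 fell and 2 rose (adjusted p = 0.0139, adjusted p = 0.431 with an estimated correlation, median -0.19 but 0.15 with median centring). Of the cholesterol synthesis genes 8 fell and 2 rose (adjusted p = 0.0443, adjusted p = 0.647 with an estimated correlation, median -0.15 but 0.09 with median centring). Median centring ended the calls of the NRF2, proteasome and cholesterol lists (adjusted p of 0.125 to 0.963).

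The 6 genes fixed for every comparison, those of CD47, its partners and the VEGF pathway, were read on the quantile scale. FLT1, which encodes VEGF receptor 1, rose by 0.67 ± 0.08 with JK exosomes (adjusted p = 3.77e-05) and by 0.73 ± 0.08 with JINB8 exosomes (adjusted p = 1.83e-05). VEGFA rose by 0.73 ± 0.13 (adjusted p = 0.000972) and 0.84 ± 0.13 (adjusted p = 0.000351). Without the normalization both genes were lower than in untreated cells by the array-wide shift, at -0.75 and -0.66 for FLT1 and -0.88 and -0.77 for VEGFA. KDR, which encodes VEGF receptor 2, changed by -1.03 ± 0.29 (adjusted p = 0.0114) and -1.34 ± 0.29 (adjusted p = 0.00245), the former by -0.67 without JK replicate 3 (adjusted p = 0.0291). CD47 had values of 0.28 ± 0.11 (adjusted p = 0.051) and 0.06 ± 0.11 (adjusted p = 0.667), THBS1 of 0.02 ± 0.07 and 0.05 ± 0.07, and SIRPA of -0.13 ± 0.09 and -0.14 ± 0.09, none past the threshold. THBS1 ranked 2 to 4 of 18417 genes on every HUVEC array, where quantile normalization sets the value (3 distinct values over 9 arrays), so its fold changes and SE on this scale say little. Nor do its values of 0.98 and 1.08 with median centring, which passed, since a constant shift is added to signals near the top of the range. With median centring KDR did not pass with JK exosomes (-0.57, adjusted p = 0.0901), while CD47 passed at 0.60 and 0.44. In the deposited values CD47 and THBS1 were lower than in untreated cells, at -1.19 and -0.81 with JK exosomes and at -1.39 and -0.76 with JINB8 exosomes.

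**Figure D3:**
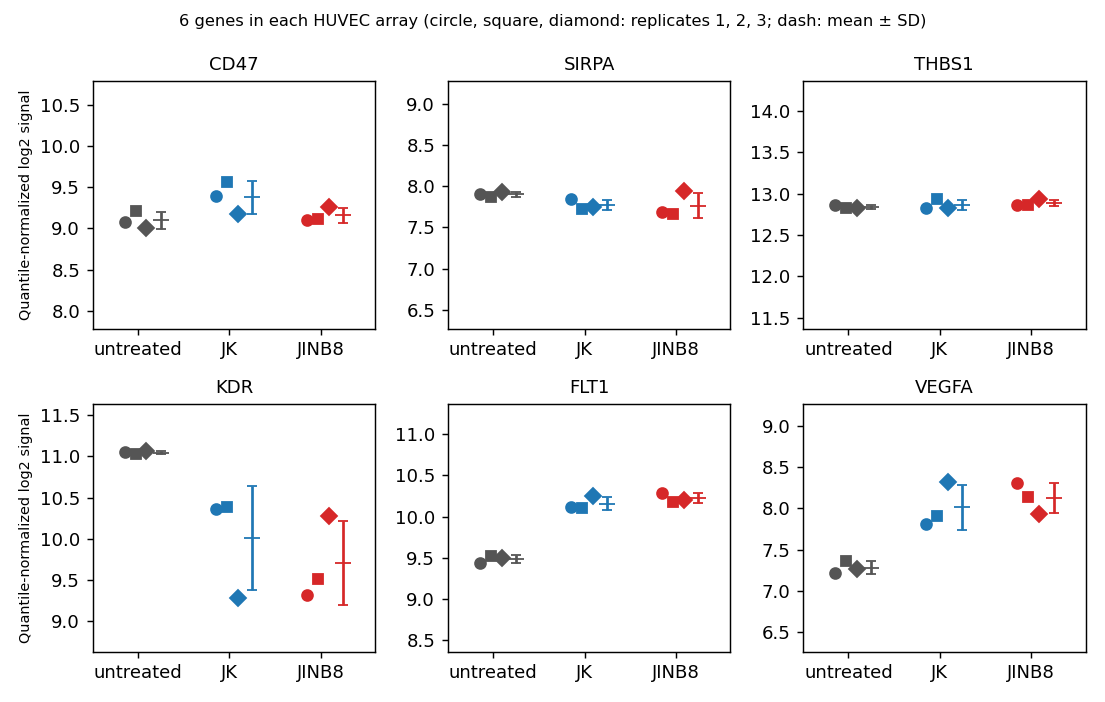
Quantile-normalized log2 signal of CD47, SIRPA, THBS1, KDR, FLT1 and VEGFA in each of the 9 HUVEC arrays, with replicates 1, 2 and 3 as circle, square and diamond and the mean ± SD of 3 arrays as a dash with bars. KDR was 10.36 and 10.38 in JK-treated replicates 1 and 2 but 9.29 in replicate 3, and 9.32 and 9.51 in JINB8-treated replicates 1 and 2 but 10.28 in replicate 3; in the deposited values FLT1 and VEGFA were lower in treated than in untreated cells.

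Across genes, which are not independent replicates, the log2 fold changes of the 2 responses correlated at r = 0.963 as deposited (covariance 0.311) and at r = 0.958 after quantile normalization (covariance 0.269). Both use the same untreated arrays. In 100 simulations of unchanged groups, drawn from each gene's pooled spread with a shared control draw, the mean r was 0.50 on either basis. Sharing the control draw fixes that value whatever the data. The simulated covariances were 0.0085 and 0.0079. After quantile normalization 4059 genes were higher in both comparisons and 3512 lower in both, where independent lists would share 1256 and 958. Lists with shared controls are not independent. The spread of the untreated arrays alone would add covariances of 0.0106 and 0.0087, small beside those observed. But this leaves out a level that all 3 untreated arrays share, and they are too few to be split. So part or all of the excess may come from the shared controls.

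The third comparison asked whether HUVEC responded otherwise to exosomes of the CD47-deficient line, by setting JINB8-treated against JK-treated cells directly. No gene passed in limma at an adjusted p under 0.05 (smallest 0.0644), and 1678 genes had an unadjusted p under 0.05, where 921 would by chance. The highest values by the naming rule, none passing, were those of OR2J3 (1.07 ± 0.33, adjusted p = 0.338), MIR221, a microRNA precursor (1.01 ± 0.14, adjusted p = 0.0644, but 1.06 with adjusted p = 0.0442 with median centring), UBLCP1 (0.98 ± 0.21), TRIM51 (0.85 ± 0.20) and SLCO4C1 (0.78 ± 0.23). The lowest were those of SNORA62 (-1.33 ± 0.25, adjusted p = 0.112), XAGE-4 (-0.97 ± 0.14), SNORA24 (-0.75 ± 0.18), OSGEP (-0.62 ± 0.15) and SCARNA17 (-0.62 ± 0.20). MIR221 and others of these passed in further alternatives, most of them with array weights. KDR differed by -0.29 ± 0.28 (adjusted p = 0.794), CD47 by -0.21 ± 0.11 (adjusted p = 0.615), VEGFA by 0.12 ± 0.14, FLT1 by 0.09 ± 0.09, THBS1 by 0.05 ± 0.09 and SIRPA by -0.03 ± 0.11, none passing.

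Of the 33 lists 8 passed camera in this contrast, 7 lower and 1 higher in JINB8-treated cells, and none held with an estimated correlation (adjusted p of 0.46 to 0.803). No member of any list passed over all genes. Of 61 cytoplasmic ribosomal protein genes 6 had a positive fold change (median -0.18, adjusted p = 1.3e-10, 0 higher and 1 lower adjusted over the list alone), with RPS27 at -0.53 ± 0.11, RPL27A at -0.48 ± 0.13 and RPL12 at -0.41 ± 0.10. Of 55 oxidative phosphorylation genes 4 were positive (median -0.18, adjusted p = 2.67e-10, 0 higher and 3 lower adjusted over the list alone), with NDUFA8 at -0.47 ± 0.11 and NDUFA7 at -0.41 ± 0.10. Mitochondrial ribosomal proteins were lower (adjusted p = 1.22e-06, MRPL16 -0.45 ± 0.14 and MRPL24 -0.37 ± 0.11), as were interferon-stimulated genes (adjusted p = 0.00097, USP18 -0.54 ± 0.20 and OAS1 -0.52 ± 0.25). The other lists lower were proteasome subunits (adjusted p = 0.00151, PSMA6 -0.42 ± 0.11), histones (adjusted p = 0.00337, H2AC6 -0.42 ± 0.13) and H/ACA small nucleolar RNAs (adjusted p = 0.00627, 0 higher and 2 lower adjusted over the list alone). The TGF-beta, YAP and matrix list was higher (adjusted p = 0.0122, 2 higher and 1 lower adjusted over the list alone), with TIMP3 at 0.42 ± 0.11 and MMP14 at 0.38 ± 0.09 but ID1 at -0.45 ± 0.13. Cyclic loess ended this upward call (adjusted p = 0.0969). The third replicates of both groups lay with the other group on the first principal component of the 6 treated arrays, which held 44.2% of their spread. Leaving out 1 array at a time gave 0 to 3 genes, and array weights, which count deviating arrays less, gave 377.

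The fourth comparison asked whether the RNA carried by the exosomes differed between the lines. CD47, in which JinB8 cells are deficient per the labels, did not separate the exosome RNAs (4.71 ± 0.02 in JK and 4.73 ± 0.19 in JINB8, SD, n = 3; log2 fold change 0.017 ± 0.094, SE, limma adjusted p = 0.988). The kind of mutation is not given in the sources used here and the signal lay below the array medians, so this value does not check the labels. JINB8 exosome RNA differed from JK exosome RNA in 125 genes, 123 higher and 2 lower (limma, adjusted p under 0.05), and 19 of the 125 differed at least 2-fold. SH3KBP1, an endocytic adaptor, was higher by 1.96 ± 0.17 (SE, n = 3 per group, adjusted p = 0.000171), FAF2 by 1.73 ± 0.12 (0.83 after quantile normalization), MPLKIP by 1.40 ± 0.13 and CDK6, a G1 kinase, by 1.34 ± 0.09. MTND2P28, a nuclear copy of a mitochondrial gene whose probes cannot be told from the original here, was higher by 1.76 ± 0.13. LDHA, lactate dehydrogenase, was higher by 1.29 ± 0.12 and the linker histone H1-4 by 1.23 ± 0.10. The chaperones HSPA8 and HSP90AB1 were higher by 1.19 ± 0.10 and 1.16 ± 0.15, and CD1E, from the T cell marker list, by 1.16 ± 0.11. The 2 lower genes were the protocadherin PCDHGB4 (-0.59 ± 0.08, adjusted p = 0.0023) and SNRPA1 (-0.41 ± 0.08, adjusted p = 0.0315).

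All 10 lists that passed camera were higher in JINB8 exosome RNA, and none held with an estimated correlation (adjusted p of 0.178 to 0.387). Of 61 cytoplasmic ribosomal protein genes 19 were higher and none lower (43 and 0 adjusted over the list alone, median 0.41, adjusted p = 1.24e-41), with RPL30 at 1.08 ± 0.12, RPL18 at 0.82 ± 0.10, RPL8 at 0.77 ± 0.08 and RPS28 at 0.77 ± 0.09. Of 51 histone genes 6 were higher (20 adjusted over the list alone, adjusted p = 1.1e-15), with H3C11 at 1.10 ± 0.13, H4C3 at 0.84 ± 0.10, H4C13 at 0.80 ± 0.12 and H2AC21 at 0.69 ± 0.11. Of 26 glycolysis and hypoxia genes 4 were higher (7 adjusted over the list alone, adjusted p = 4.96e-06), namely LDHA, ENO1 (1.16 ± 0.12), PGK1 (0.77 ± 0.11) and TPI1 (0.42 ± 0.08). HSP90AA1 (0.87 ± 0.10) and ANXA6 (0.65 ± 0.11) were among the 4 of 26 vesicle protein genes that were higher (6 adjusted over the list alone, adjusted p = 5.01e-05). In addition 3 of 16 heat shock genes were higher (7 adjusted over the list alone, adjusted p = 1.9e-09). Of 35 T cell markers 2 passed (4 adjusted over the list alone), CD1E and the transcription factor LEF1 (0.61 ± 0.08, list adjusted p = 0.000103), while CD3E (0.37 ± 0.09, adjusted p = 0.112) and CD3G (0.34 ± 0.09) did not. Of 36 proteasome genes 1 passed, PSMD8 (0.57 ± 0.09; 6 adjusted over the list alone, list adjusted p = 4.75e-05), and of 55 oxidative phosphorylation genes 1, NDUFB5 (0.50 ± 0.08; 4 adjusted over the list alone, list adjusted p = 0.000213). No member passed over all genes in the G2/M list or that of mitochondrial ribosomal proteins (adjusted p = 0.0226 for both, 1 and 4 members adjusted over the list alone), where BUB1 had 0.34 ± 0.08 and MRPL9 had 0.43 ± 0.09.

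Of the other fixed genes, KDR (0.03 ± 0.09), FLT1 (0.02 ± 0.08), SIRPA (-0.02 ± 0.07), VEGFA (-0.15 ± 0.08) and THBS1 (-0.16 ± 0.11) did not pass. Single arrays moved the number of genes called in exosome RNA: it was 54 in place of 125 without JK replicate 3, 59 without JINB8 replicate 3 and 77 without JINB8 replicate 2.

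**Figure D4:**
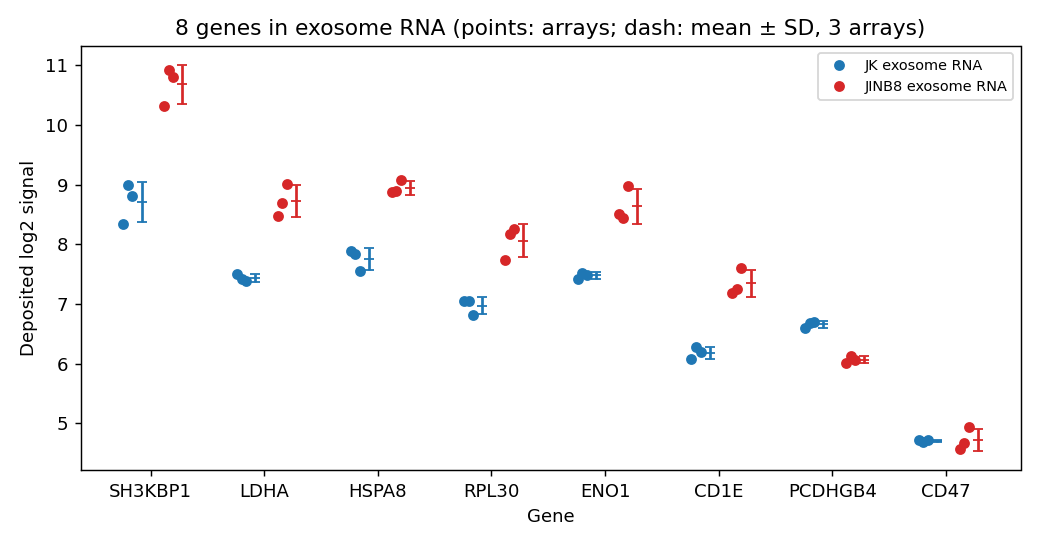
Deposited log2 signal of 8 genes in the exosome RNA arrays, JK in blue and JINB8 in red, with a point per array and the mean ± SD of 3 arrays as a dash with bars. The JINB8 arrays lie above the JK arrays for SH3KBP1, LDHA, HSPA8, RPL30, ENO1 and CD1E and below them for PCDHGB4, and overlap for CD47.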

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

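Of the tests here, those of the relation of the exosome RNA difference to the level in HUVEC and of the other splits of the arrays against untreated HUVEC were chosen before their results were seen, and the other tests only after.

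The difference between the lines was also compared between recipient cells and exosome RNA. A limma fit over all 15 arrays tested whether the JINB8-minus-JK difference in HUVEC differed from that in exosome RNA. It called 100 genes (adjusted p under 0.05), 87 lower and 13 higher in HUVEC. Each gene had 1 spread for both kinds of sample, which the main comparisons kept in separate fits. With all 15 arrays in 1 fit the direct HUVEC contrast called 93 genes in place of 0, so the 100 may depend on this pooling. The list tests that follow used the same fit. The cytoplasmic ribosomal protein list had a median of -0.18 in HUVEC and 0.41 in exosome RNA (camera adjusted p of the difference 8.33e-44). The differences of 9 further lists passed: nuclear oxidative phosphorylation (1.24e-11), histones (2.65e-10), mitochondrial ribosomal proteins (3.43e-07), proteasome subunits (6.01e-07), heat shock (0.00168), vesicle protein genes (0.00408), CD47 and thrombospondin-1 signalling (0.00799), glycolysis and hypoxia (0.0149) and interferon-stimulated genes (0.0168). The CD47 and thrombospondin-1 list was the 1 of these 10 lists whose difference went up, with medians of 0.05 in HUVEC and -0.04 in exosome RNA, and 0 of the 10 held with an estimated correlation (0.102 for ribosomal proteins). Among the 12083 probesets without a listed gene, which the main comparisons left out, 125 differed in exosome RNA, 119 higher and 6 lower with JINB8, and 0 differed between the treated HUVEC groups.

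The untreated HUVEC arrays stood apart from both treated groups. A scale that depends on intensity is argued against as the whole cause, since 9345 genes or more passed in both comparisons after cyclic loess. Loss of mural cells or fibroblasts stays open. Against the fall of TAGLN (-5.06) stands a median log2 fold change of -0.030 over 17 further markers (interquartile range 0.65), of which 6 fell and 3 rose. FAP (-1.54) and POSTN (-1.05) fell most, CNN1, THY1, COL1A2 and RGS5 fell by 0.44 to 0.56, and ACTA2 rose by 0.38. The markers thus did not fall together as TAGLN did. Dim markers have little room to fall as far as TAGLN, though FAP and POSTN, at 4.96 and 4.31 in untreated cells, did fall. The signal of HUVEC themselves would hide the loss of brighter markers such as RGS5 (11.01 in untreated cells), so the loss of these cells is not decided. Another batch, donor or culture of the untreated arrays may account for any part and cannot be told apart from the treatment, since 0 untreated arrays had a median within the range of the treated ones. Response to exosomes stays open too. With 10 splits of 6 arrays no share under 0.05 can be had, and 1 of 10, the real one, gave as many genes in each comparison. The real splits gave 18319 and 18286 as deposited and 8950 and 9074 after quantile normalization, and the highest of the others 0. Every other split mixes untreated with treated arrays, so their difference enters the spread within groups. The count of 0 follows from that and is no separate evidence.

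The third replicates of the treated HUVEC groups lay with the other group on the first principal component. On the second component, with 21.1% of the spread, they did not. There all JK arrays lay below 0 (-0.52 to -16.6) and all JINB8 arrays above it (1.51 to 11.5), with the third replicates outermost. With 10 splits of the 6 arrays no share under 0.05 can be had: the real split called 0 genes and the highest other, that with these replicates exchanged, 370. This is the structure of the samples already seen on the first principal component (44.2% of the spread) and no separate evidence of it. Scale differences between arrays are argued against: they were small, so that quantile normalization of the 6 arrays moved no value by more than 0.116, and removing them left 98.8% and 99.3% of the gaps between the third replicates and their own groups on this component. An exchange of the third replicates and a batch or day that the labels do not give both stay open and cannot be told apart. A batch common to the third replicates alone would move both the same way. Their deviations from the group means went opposite ways (r = -0.45 across genes, which are not independent replicates). The batch left open is therefore one that cuts across the replicate numbers. The exchanged split is the split on that component, so its count does not decide between them, and no source gives a batch. No array was moved.

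Of the 125 genes that differed in exosome RNA, 123 were higher with JINB8. An array-wide scale is argued against by the 107 genes that passed after quantile normalization, 100 of them higher and 7 lower with JINB8. More cellular messenger RNA in the JINB8 preparations stays open: the fold change went with a gene's signal in JK-treated HUVEC (Spearman rho 0.218 across genes, which are not independent replicates), but signals of different probes do not rank genes by abundance, so this decides nothing. The CD47 status of the producing cells stays open too, since line and CD47 status go together here and the CD47 signal itself differed by 0.017. With 10 splits no share under 0.05 can be had: the real split called 125 genes and the highest other 0.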

How the results depend on the processing

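Of the tests here, cyclic loess and every alternative around the quantile basis were chosen after seeing the data. Causes of the changes below were not tested unless the alternative's construction shows one.

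For JK-treated against untreated HUVEC, the 18319 genes of the deposited values became 8950 with quantile normalization, 10049 with median centring and 9345 with cyclic loess, all of which remove the array-wide shift. They became 10963 without the 40% dimmest genes and 32814 over all 33297 probesets, in both cases nearly all of those tested. The 10 lists (9 up and 1 down against the other genes) became 16 with cyclic loess (5 up and 11 down), 6 without the dimmest genes and 3 with an estimated correlation, all up. With fry, which tests a list against no change and so reads the array-wide shift, all 33 lists were down. For JINB8-treated cells the 18286 genes became 9074, 10475, 9535, 10935 and 32807 in the same order, the last 2 again nearly all of those tested. The 9 lists (8 up and 1 down) became 15 with cyclic loess (3 up and 12 down), 1 with an estimated correlation, up, and 33 with fry, all down for the same reason. On the quantile basis an unadjusted p with a 1.5-fold change gave 3378 and 3564 genes, and lists numbered 2 and 2 with an estimated correlation, all down, and 22 (5 up and 17 down) and 21 (3 up and 18 down) with fry.

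For JINB8-treated against JK-treated HUVEC, the 0 genes became 8 with median centring, 6 with cyclic loess, 8 without the dimmest genes, and 23 with a variance trend and robust fitting. They became 377 with array weights, 93 with all 15 arrays and 50 by unadjusted p with a 1.5-fold change. The 8 lists became 0 with an estimated correlation and 0 with fry. For exosome RNA the 10 lists of the deposited values became 0 with an estimated correlation and 0 with fry. After quantile normalization 12 lists passed camera there, 0 with an estimated correlation and 8 with fry.

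Leaving out 1 array at a time gave 18281 to 18320 and 18245 to 18300 genes for JK and JINB8 against untreated HUVEC as deposited, and 7801 to 8867 and 7830 to 9335 on the quantile basis. Lists ranged from 9 to 12 and 9 to 11 as deposited and from 11 to 14 and 9 to 14 on the quantile basis. The direct contrast gave 0 to 3 genes and 8 to 10 lists, exosome RNA 54 to 100 genes and 9 to 11 lists, and the correlation of the responses 0.943 to 0.966.

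Without quantile normalization the signs turned, by the array-wide shift, for CD47 (-1.19 with JK and -1.39 with JINB8), THBS1 (-0.81 and -0.76), FLT1 (-0.75 and -0.66), VEGFA (-0.88 and -0.77), SNORD94 (-0.39) and SNORA38 (-0.81). The other reversals were of values that did not pass. With median centring SIRPA had 0.094 and 0.12, and 0.027 in the direct contrast, and with cyclic loess CD47 had -0.010 with JINB8. Leaving out single arrays, THBS1 with JK ranged from -0.016 to 0.043 and SIRPA in the direct contrast from -0.12 to 0.033. In exosome RNA CD47 ranged from -0.088 to 0.091, SIRPA from -0.050 to 0.0030, KDR from -0.057 to 0.088 and FLT1 from -0.0098 to 0.073. The values of named genes kept direction and side of the threshold in 1020, 729, 524 and 527 cases over the 4 comparisons in the order of the report, passed anew in 9, 3, 37 and 1, and no longer passed in 3, 0, 0 and 30.

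The replicate numbers did not pair the arrays throughout. Same-numbered deviations correlated at 0.35, -0.04 and 0.07 for JK with untreated HUVEC, where the first stood above those with other numbers (at most -0.16). They correlated at -0.02, 0.05 and 0.04 for JINB8 with untreated HUVEC, at -0.20, -0.18 and -0.45 for JINB8 with JK, and at 0.03, -0.02 and -0.04 in exosome RNA. With the replicate block the counts were 18310, 18277, 0 and 104 genes, 8618 and 8810 on the quantile basis, and the correlation 0.963. No detection calls were given, so what signal over background limits was not measured.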

Other observations

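Of the tests here, that of the JINB8-enriched genes in HUVEC was chosen before its result was seen, and that of the T cell list only after.

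Transfer of exosome RNA into HUVEC was examined as a hypothesis on 2 gene sets. If T cell transcripts were carried over in bulk, the T cell marker list might be higher in treated cells. The list of 35 genes had an adjusted p of 0.684 with JK and 0.875 with JINB8 exosomes after quantile normalization, both directed downward, which decides nothing. If RNAs enriched in JINB8 exosomes were carried over, they might be higher in JINB8-treated than in JK-treated HUVEC. Their median log2 fold change was -0.066 (45 of 123 positive, camera p = 0.0143 downward and p = 0.506 with an estimated correlation). After quantile normalization it was -0.070 (camera p = 0.000263 downward at the preset correlation). A median at or below 0 was set beforehand as speaking against transfer, and the value met that bound. Camera sets these genes against the other genes (median of all genes -0.019). Whether their value lies below 0 beyond its spread was therefore not tested. Where the cells express these genes themselves their own RNA would hide a small transfer, so the bound does not decide. Transfer stays open.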
